A study of Drosophila melanogaster with 6 samples.

How the data were processed

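RNA sequencing libraries were made from total RNA of whole heads of 4-day-old female Canton S flies, a wild-type laboratory strain of Drosophila melanogaster, with standard Illumina chemistry per the labels' protocols. The labels put 3 libraries in a vitamin A deprived group and 3 in a vitamin A replete group, which differ in whether beta-carotene was in the food. The flies were kept at 25 °C and 50% relative humidity per the labels.

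The deposited files hold whole-number read counts per gene, 1 file per library, with no normalization applied. The submitters' processing notes name FastQC 0.11.5, Trim Galore 0.4.2, STAR 2.5.3a, featureCounts and Subread 1.6.2 without giving their order or settings. The genome build, the gene annotation, the treatment of reads that map to several places and whether counting used strand are not given in the sources used here. Reads of overlapping genes, antisense partners and near-identical copies can therefore not be assigned with certainty. Each file lists 17509 FlyBase gene identifiers, of which 17389 were matched to a symbol and a position in the Ensembl release 115 annotation of assembly BDGP6.54, and 120 were not. Coordinates below are those of that annotation, matched by gene identifier.

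Total counts per library ran from 15668307 to 24165187. Every deprived library was deeper than every replete one, at 21344395 to 24165187 against 15668307 to 17935321 counts. A count of 3 corresponded to 0.124 to 0.191 CPM, the count scaled by library size, and this floor covers counting error only. The labels do not say that the libraries came from separate groups of flies, so p-values measure only the spread between these samples, which may be technical. The library codes in the labels begin with different digits in the 2 groups. What the codes mark is not stated, and a batch that followed them could not be told apart from diet.

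Genes with too few reads were removed with edgeR's filterByExpr (minimum count 10, minimum total count 15), which left 10896 of the 14562 genes that had a count in at least 1 library. Deprived and replete heads were compared with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, robust dispersion estimation and group as the only term. Genes were called at a Benjamini-Hochberg (BH) adjusted p under 0.05, and fold changes are deprived over replete. The common biological coefficient of variation was 20.6%. CPM values use TMM-scaled library sizes and are given as mean ± SD over 3 libraries.

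Before the data were examined, 39 gene lists were fixed that cover vision, immunity, stress, metabolism, circadian time and the cell types of a head or of tissue carried over with it. The 38 lists with at least 5 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with BH adjustment over lists, beside camera with an estimated correlation and fry. The rule for naming genes was fixed at the same time. It takes up to 12 genes per direction with the largest fold change among called genes with a mean of at least 2 CPM and no overlap between groups. It adds all tested members of the chromophore and rhodopsin lists, up to 4 members with the smallest p of every other list, and the 5 most abundant called genes. Some further list members given below fall outside this rule.

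The alternatives set at the start were other normalizations and filters, DESeq2 1.42.0, limma-voom, glmTreat against a log2 fold change of 0.5, non-robust dispersion, the replicate number as a block, removal of 173 nuclear ribosomal RNA and mitochondrial genes, and leaving out each library in turn. Chosen after seeing the data were thinning every library to the smallest total, a covariate made of clock genes (tim, vri and per against Clk and cry) and a covariate made of oocyte genes (osk, vas, otu and aub). Replicate libraries differed by more than counting noise, with a chi-square per degree of freedom of 19.2 to 46.5 between pairs, so no pair was treated as 1 library deposited more than once. Separate preparations of the same RNA could also differ by more than counting noise. Across the 10821 tested genes with an annotated length, Spearman's rho of log2 fold change with exonic length was 0.10, where genes are not independent replicates. GC content was not checked because no genome sequence was used here.

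The fit was tested on simulated counts drawn from the means and library sizes of this comparison over 10896 genes. Of 50 genes changed at each size, 32% were called at 1.5-fold, 40% at 2-fold, 78% at 3-fold and 72% at 4-fold. There were 12 false calls among 123, and 3 calls where no gene had been changed.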

Results

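Flies make the retinal-type chromophore of their visual pigments from dietary carotenoids, so food without beta-carotene leaves them without vitamin A. Transcripts were counted in whole heads, which hold eyes, brain, fat body, muscle and cuticle, of 4-day-old wild-type females raised without or with beta-carotene (3 libraries each). The deprived libraries held 22815852, 21344395 and 24165187 counts, and the replete libraries 15668307, 17935321 and 16858163. The comparison asks which head transcripts differ when the diet lacks vitamin A. Where values are set against each other, the deprived mean comes before the replete mean.

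Vitamin A deprived heads had more transcript of ninaG and ninaB, which act in making the chromophore, and of the photoreceptor genes Cpn and eys, and less of the light-activated channel gene trpl and of Arr2, the major arrestin that shuts off rhodopsin. The largest change among the called genes was in CG11426, a predicted lipid phosphate phosphatase, which rose 13.4-fold from 13.2 ± 0.545 CPM in replete to 177 ± 10.3 CPM in deprived heads (SD, n = 3 each). Calphotin (Cpn), a calcium-binding protein of photoreceptors, rose 3.19-fold from 230 ± 26.8 to 734 ± 62.3 CPM. The amino acid transporter gene JhI-21 rose 4.38-fold from 21.7 ± 2.55 to 95.1 ± 3.89 CPM. In all, 32 genes were higher and 4 lower in deprived heads among 10896 tested (edgeR quasi-likelihood test, BH-adjusted p under 0.05).

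The deprived and replete values of all 36 called genes did not overlap, and 1186 of all tested genes (10.9%) showed such separation where chance gives 10%. Of the called genes, 17 were at least 2-fold higher and 1 was at least 2-fold lower. At an unadjusted p under 0.05, 296 genes were higher and 263 lower. Without deprived library 1, deprived library 3 or replete library 1 the count of higher genes was 20, 18 or 21, without deprived library 2 or 3 the count of lower genes was 2, and without replete library 2 it was 7; 20 calls passed in every such fit. With clock genes as a covariate, an alternative chosen after seeing the data, 12 of the 36 calls remained, while the median ratio of their fold changes (log2) to those without it was 0.99 and that of their standard errors was 1.41. That covariate partly followed diet, so a call lost with it does not tell clock state apart from diet.

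**Figure D1:**
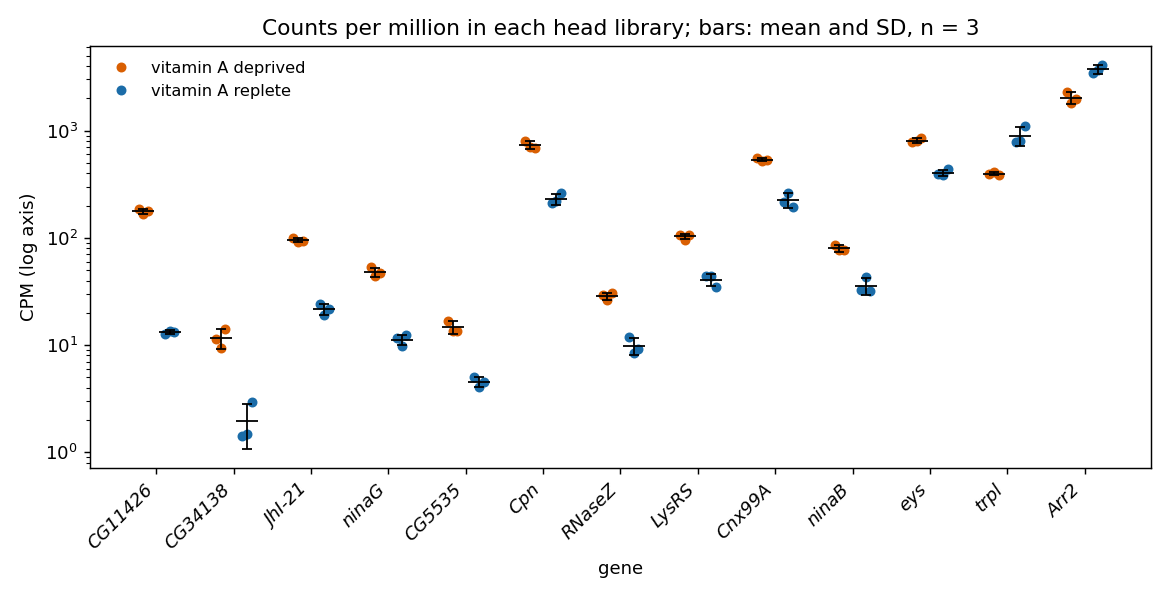
CPM on a log axis of 13 called genes in each library, with vitamin A deprived libraries in orange, replete libraries in blue, and bars for the mean and SD of 3 libraries. CG11426 lies near 177 CPM in deprived and 13.2 CPM in replete heads, and trpl and Arr2 are lower in all 3 deprived libraries than in any replete one.

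Among the 7 genes for carotenoid uptake and chromophore synthesis, ninaG and ninaB rose. The oxidoreductase gene ninaG, which acts in making the 3-hydroxy form of the chromophore, rose 4.28-fold from 11.2 ± 1.3 to 48.2 ± 4.71 CPM (edgeR quasi-likelihood, BH-adjusted p = 1.34e-05). The gene ninaB, which encodes the enzyme that cleaves carotenoids, rose 2.22-fold from 35.9 ± 6.31 to 79.8 ± 5.76 CPM (edgeR quasi-likelihood, BH-adjusted p = 0.00124). The scavenger receptor gene santa-maria, which acts in carotenoid uptake, was at 63.6 ± 3.48 against 47.9 ± 5.01 CPM and did not pass over all genes (edgeR quasi-likelihood, BH-adjusted p = 0.311). The other 4 members did not pass either: ninaD, the gut carotenoid receptor, was at 0.881 against 2.17 CPM, Pdh had a log2 fold change of -0.89, and pinta was at 13.4 against 15.4 CPM and rdhB at 39.0 against 36.2 CPM. Adjusted over the list alone, 3 members were higher and 1, ninaD, was lower. The list was called higher by camera (BH-adjusted p = 8.1e-07) and not with an estimated correlation (BH-adjusted p = 0.56 with an estimated correlation), and fry found change in either direction (mixed BH-adjusted p = 0.00011). Exons of ninaB overlap those of Adgf-D and f-cup, and its call was lost with the clock covariate (edgeR quasi-likelihood, BH-adjusted p = 0.0628, the highest of 19 alternatives).

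None of the 7 tested rhodopsin genes passed the test in edgeR, while DESeq2 called 1 lower, limma-voom called 0, and 2 were lower at an unadjusted p under 0.05. The gene ninaE, which encodes the main rhodopsin of the outer photoreceptors, was the most abundant at 11890 ± 1160 CPM in deprived and 11090 ± 976 CPM in replete heads. The ultraviolet-sensitive opsin gene Rh3 was at 294 ± 21.8 against 391 ± 19.6 CPM (edgeR quasi-likelihood, BH-adjusted p = 0.123) and Rh2 of the ocelli at 67.1 ± 2.6 against 83.4 ± 5.84 CPM (edgeR quasi-likelihood, BH-adjusted p = 0.484). These were the 2 genes that passed adjusted over the list alone. Rh4 was at 358 against 379 CPM, Rh5 at 37.2 against 61.8 CPM, Rh6 at 100 against 137 CPM and Rh7 at 25.2 against 22.5 CPM. As a list the rhodopsins were called lower (camera BH-adjusted p = 0.017, and BH-adjusted p = 0.66 with an estimated correlation), a call lost without deprived library 2 or 3 or replete library 2 or 3 and with the clock covariate (camera BH-adjusted p = 0.3).

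Of 26 phototransduction genes, trpl and Arr2 fell and stops rose. The channel gene trpl fell from 899 ± 184 to 397 ± 11 CPM, or 2.26-fold (edgeR quasi-likelihood, BH-adjusted p = 0.00124). Arr2 fell 1.85-fold from 3724 ± 336 to 2018 ± 252 CPM (edgeR quasi-likelihood, BH-adjusted p = 0.00272), a call lost with the clock covariate. The gene stops, which keeps up the level of the phospholipase C encoded by norpA, rose 1.58-fold from 60.9 ± 7.26 to 96.5 ± 9.71 CPM (edgeR quasi-likelihood, BH-adjusted p = 0.0352), a call lost without any one of the deprived libraries or replete library 1, with the clock covariate and in limma-voom, and made in 10 of 19 alternatives. The second arrestin gene, Arr1, was at 1462 ± 236 against 2200 ± 185 CPM and did not pass over all genes (edgeR quasi-likelihood, BH-adjusted p = 0.0874), although DESeq2 called it lower and inaC higher. Adjusted over the list alone, 4 members were higher (stops, inaC, rdgA and Gbeta76C) and 4 lower (trpl, Arr2, Arr1 and Cds). The other channel gene, trp, was at 1702 against 1646 CPM and norpA at 1403 against 1645 CPM. The list was called lower (camera BH-adjusted p = 0.037, and BH-adjusted p = 0.66 with an estimated correlation; fry mixed BH-adjusted p = 0.00011), and lost that call without deprived library 2 or 3 or replete library 3 and with the clock covariate (camera BH-adjusted p = 0.84).

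**Figure D2:**
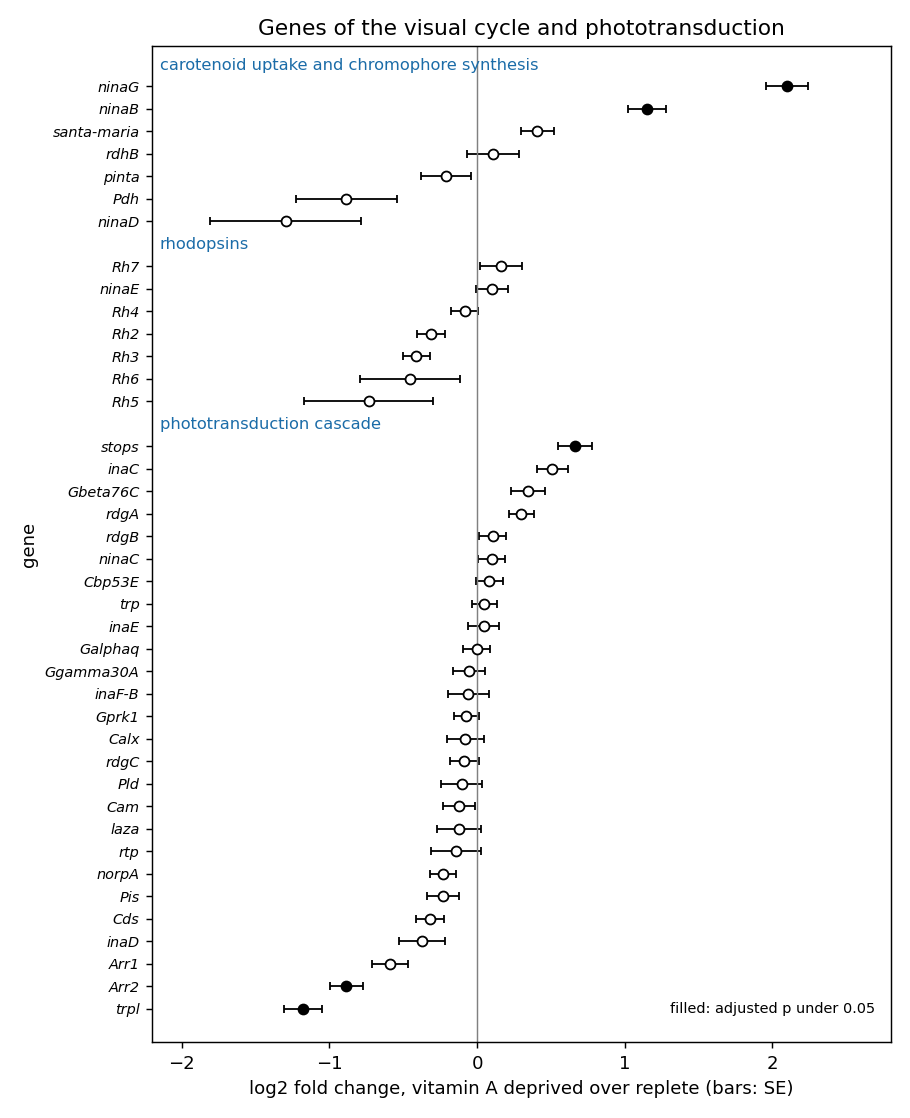
Log2 fold change of deprived over replete heads with its standard error for the tested genes of 3 lists, filled where the edgeR quasi-likelihood BH-adjusted p is under 0.05. Only ninaG, ninaB and stops are filled on the higher side and trpl and Arr2 on the lower side, while ninaE lies at 0.10.

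Among 17 genes for the maturation and transport of rhodopsin, Cnx99A, the calnexin chaperone that rhodopsin folding needs, rose 2.38-fold from 224 ± 35.5 to 534 ± 16.1 CPM (edgeR quasi-likelihood, BH-adjusted p = 0.000182). Of the endoplasmic reticulum membrane complex genes in this list, EMC1 was at 93.8 against 94.4 CPM and EMC7 at 28.6 against 30.2 CPM. EMC8-9 was at 14.7 against 17.4 CPM and EMC5 at 5.17 against 4.36 CPM. Among 13 genes of photoreceptor structure, eys, which encodes the matrix protein that keeps the rhabdomeres apart, rose 2.00-fold from 404 ± 28.3 to 807 ± 36.9 CPM (edgeR quasi-likelihood, BH-adjusted p = 0.000182). In the same list chp was at 1137 against 1056 CPM, and prom at 51.9 against 70.2 CPM did not pass over all genes (edgeR quasi-likelihood, BH-adjusted p = 0.207). Neither list was called by camera, with BH-adjusted p = 0.24 for maturation and BH-adjusted p = 0.85 for structure. In both, fry found change in either direction (mixed BH-adjusted p = 0.00011 for maturation and 0.00015 for structure). The structure list had a median log2 fold change of -0.05 while camera placed it on the higher side. Of 18 photoreceptor transcription factor genes and 18 screening pigment genes none passed in edgeR, DESeq2 or limma-voom, with 1 and 0 genes at an unadjusted p under 0.05.

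The annotation places CG11426 (FBgn0037166) on chromosome 3L at 22470556 to 22473509 (edgeR quasi-likelihood, BH-adjusted p = 1.45e-09). The non-coding RNA gene lncRNA:CR45382 lies on the opposite strand, with its nearer end 442 bases beyond CG11426. It rose 6.41-fold from 0.770 ± 0.456 to 4.99 ± 0.228 CPM (edgeR quasi-likelihood, BH-adjusted p = 0.0283). Whether counting used strand is not given, so reads of these neighbours may not be fully told apart. The remaining genes with the largest changes were CG34138 at 5.96-fold, CG31636 at 3.78-fold, CG5646 at 2.89-fold and CG9760 at 2.51-fold higher, and CG6656 at 1.63-fold lower. The gene CG34138 overlaps subdued, and it rose from 1.95 ± 0.87 to 11.6 ± 2.38 CPM (edgeR quasi-likelihood, BH-adjusted p = 0.00235). The ribosomal RNA pseudogene 28SrRNA-Psi:CR45851 was 1.80-fold lower, but its reads can come from near-identical ribosomal RNA copies and its value is uncertain. Calls for lncRNA:CR45382, CG31636, CG9760, CG6656 and 28SrRNA-Psi:CR45851 were lost without any one of the deprived libraries or replete library 1, that for CG31636 also without replete library 3 and that for CG9760 also without replete library 2.

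The transporter gene JhI-21 (FBgn0028425, chromosome 2L, 12051755 to 12056042, overlapping PLCXD) passed at an edgeR quasi-likelihood BH-adjusted p of 1.95e-06. The cationic amino acid transporter gene CG5535 rose 3.21-fold from 4.55 ± 0.479 to 14.6 ± 2.01 CPM (edgeR quasi-likelihood, BH-adjusted p = 0.00232), a call lost with the clock covariate (edgeR quasi-likelihood, BH-adjusted p = 0.0709, the highest of 19 alternatives). LysRS, which charges lysine onto its transfer RNA, rose 2.53-fold from 40.8 ± 5.46 to 103 ± 5.95 CPM (edgeR quasi-likelihood, BH-adjusted p = 0.000153). RNaseZ, which trims the 3' end of transfer RNA precursors, rose 2.92-fold from 9.83 ± 1.83 to 28.7 ± 2.16 CPM (edgeR quasi-likelihood, BH-adjusted p = 0.000905). The called genes outside the naming rule, listed after their values were seen, were LeuRS, IleRS, Bdp1, Fie, Rgk2, CG7135, Ack, cindr, Hrs, CG8034, dnr1, eIF2Bepsilon, Ttd14, Dgp-1 and homer, at 1.38-fold to 2.31-fold higher. Of these, Ttd14 acts in moving TRPL protein and was at 345 ± 2.08 against 250 ± 11.2 CPM (edgeR quasi-likelihood, BH-adjusted p = 0.0366), a call lost in each fit that leaves out 1 library. With the clock covariate all of these except Fie lost their call.

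The storage protein gene Lsp2 of the fat body rose 1.69-fold from 641 ± 97.1 to 1083 ± 152 CPM (edgeR quasi-likelihood, BH-adjusted p = 0.0373), and an antisense RNA gene overlaps it. Its relative Lsp1alpha was at 9.85 ± 3.68 against 3.58 ± 0.758 CPM and in edgeR passed only adjusted over the list alone, while DESeq2 called it higher over all genes. The yolk protein genes were at 46790 ± 5380 against 44350 ± 5210 CPM for Yp3, 17550 ± 1650 against 18320 ± 3240 CPM for Yp1 and 33500 ± 3820 against 35710 ± 4160 CPM for Yp2. The list of 13 fat body and yolk protein genes was called higher (camera BH-adjusted p = 0.0023, and BH-adjusted p = 0.66 with an estimated correlation). That call was lost without deprived library 3 or replete library 1, and the call of Lsp2 without these, deprived library 1 or replete library 3. Lsp2 was called in 10 of 19 alternatives. Its call was also lost in limma-voom, with the replicate block, with non-robust dispersion, against a log2 fold change of 0.5 and with the clock covariate.

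Of 12 Turandot and JAK-STAT genes, which respond to stress and injury, none passed in edgeR, while 5 were lower at an unadjusted p under 0.05, DESeq2 called 3 lower and limma-voom 2. TotA was at 32.3 ± 4.57 against 82.4 ± 23.7 CPM (edgeR quasi-likelihood, BH-adjusted p = 0.0763) and TotC at 7.93 ± 3.41 against 30.9 ± 10.2 CPM (edgeR quasi-likelihood, BH-adjusted p = 0.208). Both, with Diedel, passed adjusted over the list alone. The list was called lower (camera BH-adjusted p = 0.00014, and BH-adjusted p = 0.41 with an estimated correlation) and kept that call in all 6 fits that leave out 1 library. Of the signalling genes in the same list, Stat92E was at 684 against 600 CPM, hop at 56.9 against 54.9 CPM and dome at 59.6 against 64.8 CPM.

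Mitochondrial transcripts were called lower as lists by camera at the preset correlation, by small amounts. The 26 mitochondrially encoded genes had a median log2 fold change of -0.20 (camera BH-adjusted p = 5.2e-06, and BH-adjusted p = 0.66 with an estimated correlation). In that list mt:lrRNA was at 25620 ± 300 against 34300 ± 3900 CPM, and in edgeR it passed with mt:ND3 and mt:ND4L only adjusted over the list alone, while DESeq2 called mt:lrRNA and mt:ND3 lower over all genes. The share of all counts on mitochondrial genes, which includes the ribosomal RNA mt:lrRNA, was 7.41%, 7.21% and 6.86% in the deprived libraries and 8.48%, 8.26% and 8.87% in the replete libraries. Nuclear ribosomal RNA was also lower in every deprived library, at 0.012%, 0.011% and 0.012% against 0.022%, 0.014% and 0.021%. The cause of these differences in share was not tested. Of 67 nuclear genes for oxidative phosphorylation, 62 had a negative log2 fold change with a median of -0.13 (camera BH-adjusted p = 6.6e-06, and BH-adjusted p = 0.66 with an estimated correlation). Both calls were lost with the clock covariate, at camera BH-adjusted p = 0.084 and BH-adjusted p = 0.071.

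Lists that mark muscle, cuticle, odorant binding proteins and the corneal lens were also called lower, with median log2 fold changes of -0.22, -0.23, -0.17 and -0.26. Their camera BH-adjusted p values were 6.6e-06, 0.005, 0.016 and 0.037, and each was 0.66 with an estimated correlation. No member passed over all genes in edgeR, DESeq2 or limma-voom, while 5 of 21 muscle, 3 of 38 cuticle, 5 of 29 odorant binding protein and 0 of 6 lens genes were lower at an unadjusted p under 0.05. The muscle gene TpnC41C was at 15.5 ± 2.68 against 23.7 ± 1.88 CPM and the cuticle gene Cpr47Ef at 15.8 ± 1.81 against 25.0 ± 4.44 CPM. Without replete library 2, which held abdominal transcripts, camera gave BH-adjusted p = 0.07 for cuticle, BH-adjusted p = 0.29 for odorant binding proteins and BH-adjusted p = 0.19 for the lens. All 4 lists lost their call without replete library 3 (camera BH-adjusted p = 0.054 to 0.34) and with the clock covariate (camera BH-adjusted p = 0.23 to 0.98), cuticle and lens also without deprived library 3 and odorant binding proteins also without deprived library 1. The cuticle call was also lost with no filter on low counts.

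Of the 11 called lists, none passed with an estimated correlation or in the directional test of fry, and 7 of the 38 lists passed the test of change in either direction. Camera at the preset correlation also called 3 to 10 lists in every split of the libraries that mixed the diets. The number of called lists therefore hardly exceeds that of mixed groups. Camera gave BH-adjusted p = 0.73 for 17 neuronal genes, which passed the test of change in either direction (fry mixed BH-adjusted p = 0.0099), BH-adjusted p = 0.66 for 15 glial genes and BH-adjusted p = 0.85 for 14 haemocyte genes. The 30 antimicrobial peptide and Bomanin genes had BH-adjusted p = 1, the 13 heat shock genes BH-adjusted p = 0.66 and the 85 cytosolic ribosomal protein genes BH-adjusted p = 0.62 by camera. The antimicrobial list was called higher without replete library 1 or 2 and lower without replete library 3 or with the clock covariate, and the ribosomal list higher without replete library 2 and lower without deprived library 1 or replete library 3. Of 19 endoplasmic reticulum stress genes, Herp at 68.2 ± 7.71 against 48.6 ± 3.49 CPM and Ire1 at 107 ± 5.51 against 84.0 ± 6.79 CPM passed only adjusted over the list alone, and the list did not pass (camera BH-adjusted p = 0.19).

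Single libraries stood apart in transcripts that varied within the diet groups. Principal component 1, with 35.9% of the variance, had replete library 2 and replete library 3 at its ends. The oocyte transcript osk was at 7.91, 20.5 and 6.06 CPM in the deprived and at 39.9, 17.9 and 0 CPM in the replete libraries. The oenocyte gene Cyp4g1 had 2670 counts in replete library 2 and 36 to 90 in the others, and the eggshell gene Cp38 had 433 counts there and at most 18 elsewhere. The clock gene tim was at 338, 348 and 550 CPM in deprived and at 455, 238 and 87.6 CPM in replete libraries, while Clk was at 47.8, 42.3 and 44.1 against 45.9, 70.2 and 94.8 CPM. The clock gene per did separate the diets, 2.01-fold higher in deprived heads, without passing (edgeR quasi-likelihood, BH-adjusted p = 0.932). The fixed list of 16 clock genes did not pass (camera BH-adjusted p = 0.89), with 1 gene higher and 4 lower at an unadjusted p under 0.05. The log2 clock index behind the covariate was 1.65, 1.8 and 2.35 in deprived and 1.8, 0.56 and -1.02 in replete libraries, so it partly followed diet. Without replete library 2 the test called 32 genes higher and 7 lower, and without replete library 3 it called 28 and 6.

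**Figure D3:**
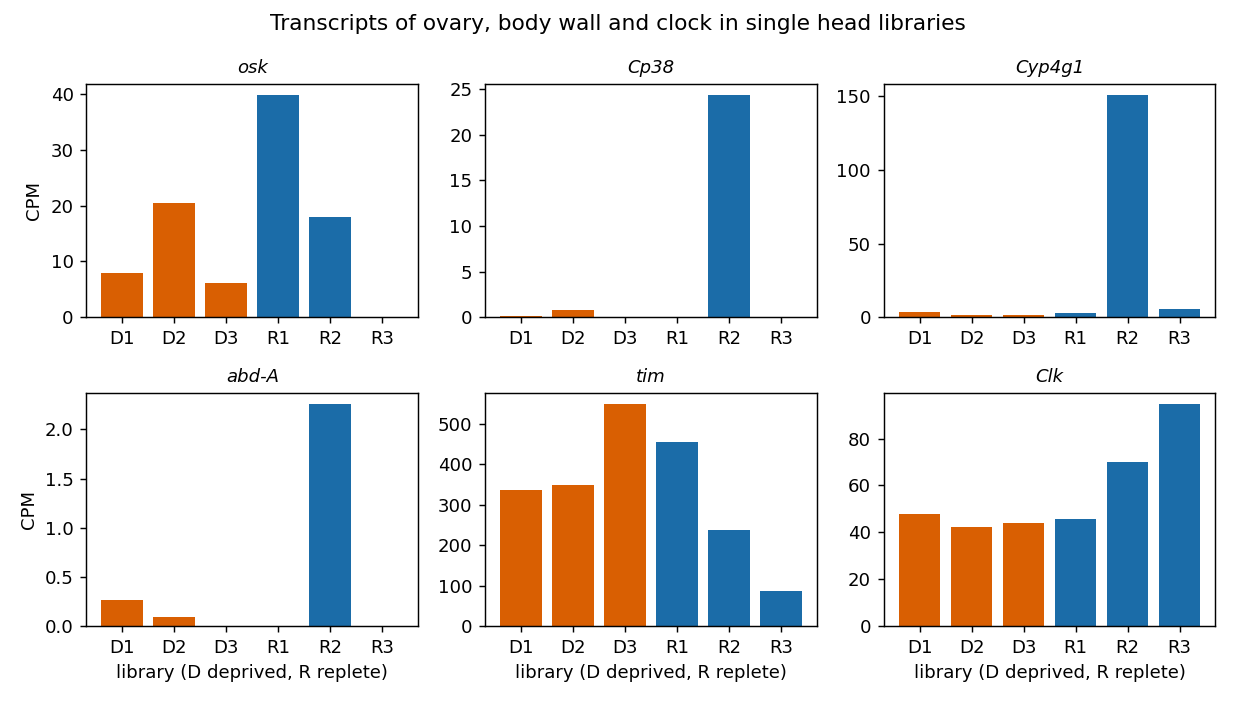
CPM of 6 transcripts in each library, with deprived libraries D1 to D3 in orange and replete libraries R1 to R3 in blue, 1 bar per library. Cp38, Cyp4g1 and abd-A are high in R2 alone, at 24.4, 151 and 2.26 CPM, and tim is lowest where Clk is highest, in R3.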

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

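Thinning and the clock and oocyte covariates were chosen after seeing the data. All 36 called genes kept their direction in every one of the 19 alternative fits that tested them (35 without ribosomal RNA and mitochondrial genes), and 12 were called in all 19: CG11426, ninaG, CG5646, Cnx99A, LysRS, RNaseZ, JhI-21, eys, CG34138, Cpn, Fie and trpl. As no called gene overlapped between groups, leaving out 1 library could hardly turn its direction, and all fits reuse these libraries. The count of higher genes (32) was 53 in DESeq2, 14 against a log2 fold change of 0.5 and 12 with the clock covariate, and that of lower genes (4) was 21, 1 and 3; lower genes numbered 10 with no filter and 7 with the oocyte covariate. Thus 89% of the calls were higher, against 72% in DESeq2. Leaving out 1 library gave 18 to 32 higher and 2 to 7 lower genes. Called lists (2 higher, 9 lower) numbered 0 and 0 with an estimated correlation and in fry, lower lists 2 with the clock covariate, and leaving out 1 library gave 2 to 4 higher and 5 to 9 lower, with 4 higher without deprived library 1 or replete library 2 and 5 lower without deprived library 3 or replete library 2. Thinned to the smallest library, 31 genes were higher and 4 lower. Turns of sign were followed only for genes of the naming rule whose log2 fold change was called or exceeded its standard error. Those that turned, none called, were CG40006 (0.03), Crys (0.05), BomBc1 (-0.03), Obp99a (-0.07) and cry (0.01) with the clock covariate. Because cry is itself part of that covariate, its value there is partly fixed by construction. Rip11 (0.01) and Rab1 (0.03) turned without replete library 2 (their lowest without 1 library, -0.25 and -0.29, came without replete library 1). The antimicrobial list turned to higher without replete library 1 or 2 (camera adjusted p = 0.027 and 0.021; 0.0037 to 0.87 without 1 library), and the cytosolic ribosomal protein list without replete library 2 (camera adjusted p = 3.7e-06; up to 0.24 without 1 library). The cause of the turns other than that of cry was not tested. With the replicate number as a block, 24 genes were higher and 6 lower, sharing 22 and 2 with the main counts. After each gene's group mean was taken off its log2 CPM, same-numbered libraries correlated at -0.06, 0.02 and 0.18. Differently numbered libraries correlated at -0.16 to 0.18, and not every sample correlated best with its own number. These values gave no clear sign that the numbers pair the samples, and they cannot exclude it.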

Other observations

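Of the tests in this part, those on eggshell genes, on diet as the source of the oocyte transcripts and on both explanations of the clock genes were chosen after the result was seen, as were the lists of transfer RNA synthetases, amino acid transporters and eIF2B subunits. Among the synthetases that charge cytosolic transfer RNA, LysRS, LeuRS and IleRS rose 2.53-fold, 2.31-fold and 1.87-fold over all genes, and with the clock covariate LeuRS (edgeR quasi-likelihood, BH-adjusted p = 0.0709, the highest of 19 alternatives) and IleRS lost their calls. Of 18 tested members, 13 had a positive log2 fold change, and in 10 every deprived value lay above every replete value. Chance puts 5% of single genes on that side. That share is no yardstick for this set, which was picked for its called members and whose members vary together (estimated correlation 0.52). GluProRS was at 113 against 79.5 CPM, AsnRS at 60.7 against 42.0 CPM and CysRS at 27.7 against 18.4 CPM, and 9 members were higher adjusted over the list alone, which is not independent evidence for a list picked from these libraries. Of the 15 tested synthetases of mitochondria, 12 had a positive log2 fold change, so the sign alone does not set the cytosolic set apart. In 2 of them the values were separated in that way, and the median log2 fold change was 0.15 against 0.40 for the cytosolic set.

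Of 11 tested amino acid transporter genes of the cationic and heterodimeric families, JhI-21 and CG5535 rose, and the median log2 fold change was 0.04. In this set slif was at 17.9 against 20.6 CPM, mnd at 21.2 against 20.6 CPM and sbm at 159 CPM in both groups. CD98hc, the heavy chain partner of JhI-21 type transporters, was at 168 against 128 CPM (edgeR quasi-likelihood, BH-adjusted p = 0.0963). The 5 subunits of eIF2B, a translation initiation factor, had log2 fold changes of 0.08 to 0.79, and eIF2Bepsilon was the one that passed, a call lost in each fit that leaves out 1 library.

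The positive median of the cytosolic transfer RNA synthetases, a set picked after its called members were seen and of which 3 of 18 passed over all genes, was weighed against oocyte RNA, depth and time of collection. The median log2 fold change of 0.40 was 0.39 with the oocyte covariate, which lowered the median standard error of 17 maternal transcripts from 0.69 to 0.29. The oocyte score was 1.7, 2.95 and 1.25 in deprived and 4.01, 2.81 and -2.42 in replete libraries. A covariate this balanced between groups could hardly change a group difference, so the value of 0.39 decides little. A score that did not follow the groups is still no ready source of a difference between them. The median was 0.40 after thinning to equal totals, but random thinning leaves expected fold changes as they are, so the bound set for it could not exclude depth. Depth cannot be told apart from diet because it follows the groups. With the clock covariate it was 0.25, between the bounds set beforehand, so a part played by time of collection stays open, as does diet, which was not tested apart from the groups. Against replete library 1 alone, whose clock index of 1.80 lies within the deprived range of 1.65 to 2.35 although per lies below it, the median log2 difference of the synthetases was 0.18, against 0.39 over all 3 replete libraries, and 1 library excludes nothing.

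Oocyte transcripts differed widely between these head libraries, and RNA from oocytes, ovaries or eggs in some samples is a candidate source. Over the 6 libraries, 17 maternal transcripts had a median Pearson r of 0.82 with a score made of osk, vas, otu and aub. Single values ran from -0.44 for tud to 0.99 for piwi. The score was -2.42 in replete library 3 and 1.25 to 4.01 in the others, so these values may lean on that library. In replete library 1, the richest in osk, eggshell genes summed to 3.13% of the oocyte genes, which argues against whole ovaries with mature follicle cells there, while in replete library 2 they summed to 194%. Replete library 2 also held abd-A (40 counts, at most 6 elsewhere), Cyp4g1, and the gut protease gene Jon99Ciii (70 counts, at most 1 elsewhere), so abdominal tissue may have been carried over into that library. The score did not separate the diet groups, since all 3 deprived libraries lay between the lowest and the highest replete score. That range was set by single libraries, and 3 libraries per group cannot exclude a part played by diet.

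Clock genes set replete library 3 apart, with tim at 87.6 CPM and Clk at 94.8 CPM. Over the 6 libraries the mean of tim, vri and per ran against that of Clk and cry (Pearson r = -0.96, exact permutation p = 0.014; Spearman rho = -0.66, exact permutation p = 0.18; 1 relation tested). These genes were picked after replete library 3 was seen, and without replete libraries 3 and 2, the farthest from the median, r was -0.42, so the relation rests on those samples and different times of collection stay open rather than supported. Clk and cry were on average 0.81 higher (log2) in replete library 3 than in replete library 1, where a smaller share of clock-bearing tissue alone would lower them. Clk had already been seen to be high there, and 1 library is set against 1 other, so this is not an independent test. The labels give no time of collection, and no biological explanation was tested.

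In other splits of the 6 libraries into 3 and 3, the highest count of called genes was 2 against 36 in the real split, and the highest count of called lists was 10 against 11. For each, 1 of the 10 splits reached the real count, the real one itself, and 10 splits are too few for a share under 0.05.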
